A study of Mus musculus with 8 samples.

How the data were processed

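The samples were polyribosome-associated mRNA from the prefrontal cortex and the hippocampus of C57BL/6 mice, taken 1 h or 6 h after a session in a conditioning chamber. Contextual fear conditioning pairs a chamber with foot shock, and the control mice were exposed to the context alone, per the labels. Messages that carry several ribosomes sediment with polyribosomes, so the measurement is aimed at mRNA loaded for translation, and no total RNA was analysed here. The libraries also held untranslated RNA: Malat1, a nuclear noncoding RNA, had an average abundance in edgeR of 11.82 on the log2 CPM scale, beside 11.83 for Camk2a. The mean of its log2 CPM over the libraries was lower, 10.93. A difference between libraries is therefore not by itself a difference in translation. There were 8 libraries, 1 for each combination of 2 tissues, 2 training states and 2 times, so no combination had a replicate. Whether both tissues came from the same mice is not given in the sources used here, and the extraction protocol in the labels describes the prefrontal cortex without naming the hippocampus. The design text names 8 adult mice and the prefrontal cortex alone, while 4 of the 8 libraries are labelled hippocampus. Nothing in the labels says how many animals went into a library, so the p-values measure only the spread between these samples, part of which may be technical.

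Per the labels' protocols, ribosomal RNA was removed, cDNA was primed with random hexamers and poly A primers, amplified isothermally (SPIA), and amplified again by PCR with sequencing adapters. The authors deposited 1 table of whole-number read counts per RefSeq transcript, not normalised. Per the submitters' processing notes, CASAVA 1.7, TopHat 1.3.1, edgeR 2.612, limma 3.12.3 and the mouse build mm9 were used, with no role or order stated. The counting program, its handling of reads shared between transcripts and its use of strand are not given in the sources used here. Isoforms of a gene, near-identical family members such as histones, ribosomal proteins and globins, and genes that overlap on opposite strands could therefore share reads, and their values are uncertain to that extent. Reads amplified without molecular identifiers are not independent molecules, so every counting interval covers counting error only.

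The table held 28157 rows with 27304 distinct identifiers, of which 97.9% were matched to a gene symbol through RefSeq and GENCODE tables of assembly GRCm38. That assembly served for names, GC content and transcript length, and no coordinates were used, since the counts were made on mm9. The symbols numbered 21643. The 594 rows that were not matched to a symbol held between 1.19% and 1.99% of a library's counts and stayed in the tests by identifier. All columns of the table belonged to the 8 libraries. A gene with several rows was represented by its row of highest total count wherever genes, not rows, were counted.

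Tests were run in R 4.3.3. The main test was the quasi-likelihood test of edgeR 4.0.16 (robust fit) on the deposited counts with TMM factors, edgeR's default low-count filter and Benjamini-Hochberg adjustment at 0.05. The fits held all 8 libraries. For the training effect over both tissues and times, the tissue effect and the time effect, the 4 remaining combinations entered as a block, which left 3 residual degrees of freedom. For training within a tissue or within a time, and for the 2 interactions, training was nested and 2 residual degrees of freedom remained. A fold change is on the log2 scale with its standard error (SE), positive in conditioned, hippocampus or 6 h libraries. CPM values were computed with TMM factors. Single combinations of tissue and time, with 1 control and 1 conditioned library each, had no test: log2 ratios of CPM with a prior count of 2 are given, and a list's median is placed by its percentile among 10000 random lists matched on mean expression. For the 11 fixed genes at 6 h, exact intervals for the ratio of 2 counts were computed at 95% confidence.

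Gene lists, 38 in number, were written before the data were examined, as were the designs, the rule for named genes and the first set of alternatives. Lists with at least 5 tested rows were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01. These tests ran over all rows of a list's genes, with adjustment within each comparison. Beside camera stand camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. No list passed with an estimated correlation in any comparison. Of a list, the number of genes passing over all rows tested and the number passing when adjusted over the list alone are given.

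Named genes were the 8 largest rises and falls among rows that passed, had an average log2 CPM in edgeR of at least 2 and moved in the same direction in every stratum. Where fewer than 5 rows passed, the 5 of smallest p in each direction were named as not passing. To these were added Fos, Arc, Egr1, Npas4, Nr4a1, Bdnf, Homer1, Junb, Fkbp5, Sgk1 and Camk2a for training, up to 4 members of each described list by smallest p, and for single combinations the 5 largest ratios in each direction at a mean log2 CPM of at least 4. Names outside this rule are said to be so.

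The libraries were compared in pairs by the variance of their count differences relative to sampling noise, over rows with a summed count of at least 20. The 2 libraries labelled conditioned 1 h agreed within sampling noise and count as 1 sample in every mean ± SD, while log2 changes and their SE come from fits that hold both unless the pair is said to be summed or left out. GC content and length were known for 97.5% of rows, and their trend in each library, a natural spline with 5 degrees of freedom, was removed through offsets in added fits. Alternatives in that set were RLE and upper-quartile factors, no filter and a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, a fit without robust weights, 1 row per gene, other designs, summed tissues and each library left out in turn. Fits without the conditioned 1 h pair (6 libraries), with the pair summed (7 libraries), without the pair and the hippocampus control 6 h library (5 libraries), list tests with the pair summed, and those with GC and length offsets were added after the data were seen. With 6 libraries no conditioned library remains at 1 h, so training is compared at 6 h alone. Upper-quartile factors moved the median of all rows for time by -0.15, and the median of every list called for time is farther from 0 than that. For the other comparisons the scalings moved that median by less.

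The pipeline was tested on simulated counts with 200 changed rows per comparison. Of rows changed by a fold of 2, edgeR recovered 31% for training over both tissues and times, 23% for tissue and 44% for time. Of rows changed by a fold of 4 it recovered 75%, 78% and 82%. At a fold of 4, recovery was 69% for training in cortex, 64% in hippocampus, 53% at 1 h and 52% at 6 h, but 35% for the training by tissue interaction and 0% for the training by time interaction. For tissue with 6 libraries, recovery was 12% at a fold of 2 and 66% at a fold of 4. The simulated libraries were independent, unlike the conditioned 1 h pair, so recovery with the pair counted once was not measured, above all for 1 h. Without a simulated trend, false calls ranged from 0 (tissue) to 16 (training in hippocampus) with 8 libraries. A simulated GC trend produced 2357 false calls for time, and 8 after the trend was removed. That trend was linear in GC content, had no length part and was the same in all libraries of a time. The real trends differed between libraries, so how well they were removed was not measured. Scripts ran in R and Python 3.11.15 with numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.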

Results

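Polyribosome-associated mRNA was counted in 8 libraries, 4 from conditioned and 4 from control mice, so that each tissue at each time was represented by 1 conditioned and 1 control library. The cortex libraries held 3610646 counts (control 1 h), 4048541 (conditioned 1 h), 5275822 (control 6 h) and 5296986 (conditioned 6 h). The hippocampus libraries held 3931321 (control 1 h), 3827831 (conditioned 1 h), 2370973 (control 6 h) and 4378917 (conditioned 6 h). Between 13607 and 15341 genes had counts in a library. Snap25, a protein of synaptic vesicle release, was the most abundant gene in 7 libraries, with 0.68% to 2.46% of the counts. In the hippocampus control 6 h library the most abundant gene was Kif5c, a kinesin motor of neuronal transport, with 8.01% of the counts and 80063 CPM before scaling. Kif5c stood at 5450 CPM in the hippocampus conditioned 6 h library and between 382 and 711 CPM in the others. At an equal depth of 1592179 counts, Kif5c left out, 13606 genes had counts in the hippocampus control 6 h library and 14307 to 14608 in the other libraries.

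The libraries labelled cortex conditioned 1 h and hippocampus conditioned 1 h held the same messages, those of both tissues among them at levels between the controls. Messages that were high in the hippocampus control 1 h library lay midway between the 1 h controls in both, at a median position of 0.46 and 0.43 on a scale from 0 (cortex control) to 1 (hippocampus control) over 111 genes. For 101 genes that were high in the cortex control the positions were 0.41 and 0.38. Markers of hippocampal excitatory neurons had a mean log2 CPM of 4.79 and 4.71 in the libraries of the pair, against 3.02 in the cortex control and 5.50 in the hippocampus control at 1 h. Markers of striatal projection neurons stood at 3.65 and 3.73, between 4.57 in the cortex control and 2.66 in the hippocampus control. The libraries of the pair agreed within sampling noise: over 11599 genes their variance ratio averaged 1.06, where 1 is counting noise alone, 0 genes passed at an adjusted p of 0.05 and 4.9% had an unadjusted p under 0.05. The next closest pair, cortex control 1 h and the library labelled hippocampus conditioned 1 h, had a ratio of 4.76, and the 1 h controls of the 2 tissues had 18.59. They were counted as 1 sample in n, and every comparison that uses them rests on their labels.

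**Figure D1:**
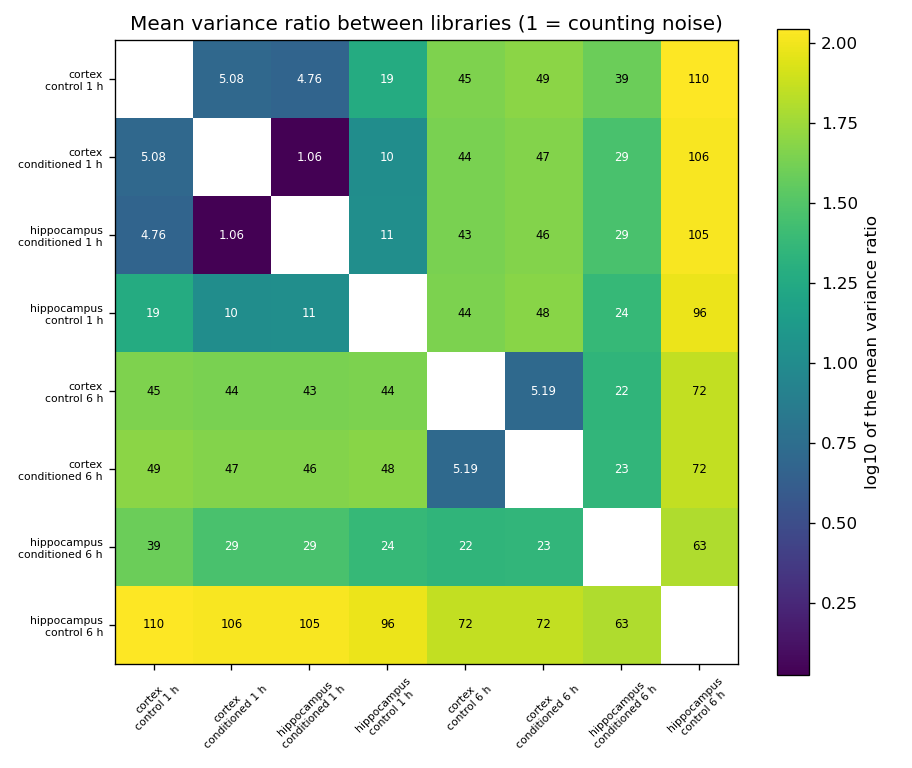
Mean variance ratio between each pair of the 8 libraries, where 1 is the ratio of counting noise alone. The libraries labelled conditioned 1 h stand at 1.06, and every other pair at 4.76 or more.

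The comparison of hippocampus with prefrontal cortex checks the tissue labels. Without the conditioned 1 h pair, messages of hippocampal principal neurons were higher in the hippocampus and messages of cortical and striatal neurons were higher in the cortex (n = 3 libraries each). Dsp, a desmosomal protein found in dentate granule cells, had 397 counts in the hippocampus and 1 in the cortex, a ratio of 534 with a counting interval of 95.3 to 21150. C1ql2, a secreted synaptic protein of granule cell terminals, had 344 counts against 3 (ratio 154, interval 52.4 to 752). Npy2r, a receptor of neuropeptide Y, had 414 counts against 26 (ratio 21.4, interval 14.4 to 33.2), a log2 change of 4.77 (SE 0.47, adjusted p = 5.78e-06). Prox1, the transcription factor of dentate granule cells, stood at 198 ± 69.3 CPM (mean ± SD) against 19.3 ± 1.81 CPM, a log2 change of 3.30 (SE 0.35).

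Of 22 tested markers of hippocampal excitatory neurons, 15 were higher in the hippocampus and 17 passed when adjusted over the list alone. They included St18 (4.27), Lct (4.63), Tspan18 (5.32), Zbtb20 (2.59) and Nr3c2, the mineralocorticoid receptor (2.41). The list rose by camera (adjusted p = 3.055e-25) and by fry (adjusted p = 0.00785), with an adjusted p of 0.26 under an estimated correlation. Of 20 markers of cortical excitatory neurons, 7 were lower in the hippocampus and 3 higher, and 14 passed when adjusted over the list alone. The lower ones included Lamp5 (-2.67), Foxp2 (-3.34) and Mef2c (-2.51), and the higher ones were Tshz2 (1.74), Nr4a2 (1.23) and Etv1 (1.17). Of 9 striatal markers, 5 were lower in the hippocampus, among them Penk (-2.33), Ppp1r1b (-2.85), Drd1 (-2.58) and Tac1 (-2.34), and 7 passed when adjusted over the list alone. The camera adjusted p was 3.544e-05 for the cortical list and 1.116e-09 for the striatal list, and 0.855 for either with an estimated correlation. Among glia, the oligodendrocyte list was higher in the hippocampus (camera adjusted p = 3.544e-05, and 0.855 with an estimated correlation, 14 of 14 genes with a positive change, 5 passing when adjusted over the list alone), although Mal, a myelin proteolipid, was the only member that passed over all rows (1.26). The astrocyte list was higher as well (adjusted p = 0.0443, and 0.855 with an estimated correlation), with Gfap, an intermediate filament protein, at 1.82 as its 1 passing gene. Thalamic markers (adjusted p = 0.00155, Prkcd 1.88) and long noncoding RNAs (adjusted p = 0.0445, Gas5 1.52) were also higher by camera, and circadian clock genes (adjusted p = 0.00279), oxidative phosphorylation (adjusted p = 0.00992) and globins (adjusted p = 0.0443) were lower with no gene passing. These 5 lists too had an adjusted p of 0.855 with an estimated correlation.

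With 6 libraries 541 of 15555 rows passed, 246 higher in the hippocampus and 295 lower, for 389 genes. The genes with the largest falls were Tnnc1, the cardiac and slow-muscle troponin C (1 count in the hippocampus against 194, ratio 144, interval 25.6 to 5724), and Igfn1 (1 count in the hippocampus, ratio 91.4, interval 16.1 to 3640). Abi3bp (-4.67), C130074G19Rik (-4.35), Myl4 (-4.29), Rasgef1c (-3.81) and Stard8 (-3.47) followed, and Slc9a4 (5.93), Serpina3g (5.58) and Lhx9 (4.93) were among the largest rises. The planned fit of all 8 libraries passed 0 of 15514 rows in edgeR, with 1493 at an unadjusted p under 0.05. DESeq2 passed 245 rows there and limma-voom 0, and without the library labelled cortex conditioned 1 h or hippocampus conditioned 1 h edgeR passed 522 or 496. All 529 of the 541 rows that were tested in the 8-library fit had the same direction in it. Its lowest adjusted p, 0.265, was shared by St18 (3.33), Nr3c2 (1.89), Shisa6, an AMPA receptor auxiliary protein (3.55), Dcn (2.74) and Thsd4 (2.38) among higher genes and Foxp2 (-2.59), Htr2a, the serotonin 2A receptor (-1.82), Fign (-1.82), Gucy1a1 (-1.55) and Ptgfrn (-2.11) among lower ones. The 8-library camera tests called 9 lists, with adjusted p from 0.795 to 0.818 under an estimated correlation.

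**Figure D2:**
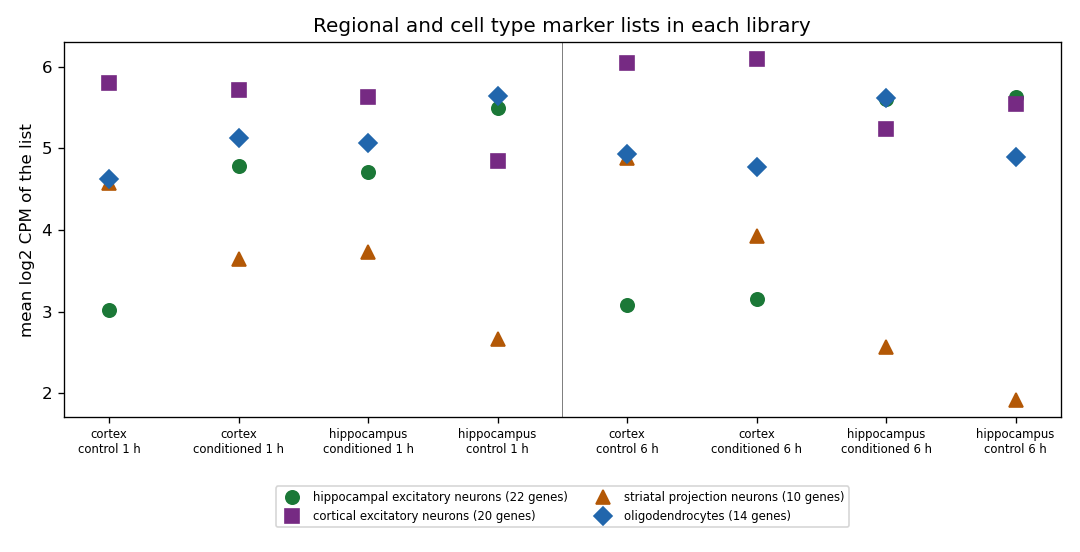
Mean log2 CPM of 4 lists of marker genes in each of the 8 libraries. Markers of hippocampal excitatory neurons lie at 3.02 to 3.15 in the cortex libraries outside the conditioned 1 h pair and at 5.50 to 5.63 in the hippocampus ones, with the pair at 4.79 and 4.71.

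The comparison of 6 h with 1 h covers time after the session together with time of day and handling, which the labels do not separate. At 6 h, messages of cytosolic and mitochondrial ribosomal proteins, of oxidative phosphorylation, of histones and of immediate early genes were lower, and messages of GABA-A receptors and of translational repressors were higher, the last 2 groups only as long as the trend with GC content and length was left in. Rplp1, a ribosomal stalk protein, fell from 51.4 ± 16.8 CPM at 1 h (n = 3, the pair counted once) to 7.34 ± 3.73 CPM at 6 h (n = 4), a log2 change of -2.65 (SE 0.36). Cox4i1, a subunit of cytochrome c oxidase, fell by 2.64 on the log2 scale (SE 0.58). Nr4a1, an orphan nuclear receptor induced by neuronal activity, changed by -2.30 (SE 0.23), and Arc, a synaptic protein whose mRNA moves to active dendrites, fell from 100.3 ± 30.9 CPM to 32.9 ± 18.1 CPM (-1.68).

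By group, 55 of 56 replication-dependent histones fell (median -1.92, camera adjusted p = 3.844e-17 and 0.854 with an estimated correlation), although histone copies share reads and are not independent. Of 82 cytosolic ribosomal protein genes, 45 fell and 1, Rpl4 (0.75), rose (adjusted p = 5.33e-10 and 0.854 with an estimated correlation), with Rpl8 at -1.87. Of 76 oxidative phosphorylation genes, 48 fell and 3, Cycs (0.87), Cox7b (0.56) and Ndufs4 (0.71), rose (adjusted p = 1.01e-07 and 0.854 with an estimated correlation). Of 75 mitochondrial ribosomal protein genes, 24 fell and 6 rose (adjusted p = 0.00301 and 0.854 with an estimated correlation). Of 36 immediate early genes, 18 fell, 3 rose and 24 passed when adjusted over the list alone (adjusted p = 0.000623, 0.0439 by fry and 0.854 with an estimated correlation). With the conditioned 1 h pair summed, the list was not called by fry (adjusted p = 0.143). Egr1 (-1.52), Egr2 (-2.58), Egr4 (-1.90), Fos (-2.01) and Junb (-1.94) were among those that fell, and Klf6 (1.47), Rgs2 (1.11) and Tiparp (0.93) rose. Of 21 glucocorticoid-responsive genes, 6 fell and Klf9 (1.79) rose (adjusted p = 0.00348 and 0.854 with an estimated correlation). Those that fell included Per1 (-1.28), a clock gene that the immediate early list also holds, Mt1, a metallothionein (-1.24), and Sgk1, a kinase induced by corticosterone (-0.97). Of 5 globin rows, which share reads, 3 passed as lower (adjusted p = 0.0336 and 0.854 with an estimated correlation). Of 14 genes of GABA-A receptors and their anchors, 10 rose, Gabra4 (1.51) among them, and Gabrd, the delta subunit of extrasynaptic receptors, fell (-2.03), with a camera adjusted p of 0.000341 and one of 0.854 with an estimated correlation. Of 34 translational repressors and RNA-binding proteins, 16 rose and 4 fell (adjusted p = 0.000623 and 0.854 with an estimated correlation), with Fmr1, the fragile X protein (1.64), Rps6kb1, the S6 kinase (1.82), Pum2 (1.17), Stau2 (1.16) and Fxr1 (1.40) among the rises.

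Of 15514 rows, 7146 passed for time, 3813 higher at 6 h and 3333 lower, with upper-quartile factors giving 3104 higher and 3957 lower. The largest rises were Spata9 (3.48), Smc4 (3.26), Lrriq1 (3.16), Taf1d, Ppig, Hmgn5, Cep290 and Gtpbp10 (2.92), in order of size and with adjusted p from 0.00207 to 0.00273. The largest falls were Bax, a promoter of apoptosis (-3.13), Rpph1, the RNA of RNase P (-3.03), C1qtnf4 (-2.81), Uqcrq (-2.69), Timm13 (-2.69), Grcc10 (-2.67), Rplp1 and Cox4i1. Libraries at 6 h stood apart from those at 1 h in base composition. The log2 ratio of 6 h to 1 h among cortex controls had a rank correlation of -0.74 with transcript GC content across 8427 genes, and GC content and length accounted for 54.4% of its variance (56.4% among hippocampus controls). Genes are not independent replicates. After the GC and length trend was removed 2151 rows passed, and 1442 of the 6965 called rows with known GC content were among them. Of the lists, histones (camera adjusted p = 3.703e-08, median over their rows -0.53), oxidative phosphorylation (3.964e-07, -0.48), cytosolic ribosomal proteins (3.609e-06, -0.45), immediate early genes (0.000771, -0.41) and mitochondrial ribosomal proteins (0.00914, -0.40) were still called lower without the trend. GABA-A receptors (0.669), translational repressors (0.895), glucocorticoid-responsive genes (0.0808) and globins (0.857) were not called then. With the conditioned 1 h pair summed to 1 library 6063 rows passed, without the pair 3326, without the pair and the hippocampus control 6 h library 1148, and without the cortex control 1 h, cortex control 6 h, cortex conditioned 1 h or cortex conditioned 6 h library 3011, 2938, 4540 or 4486.

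**Figure D3:**
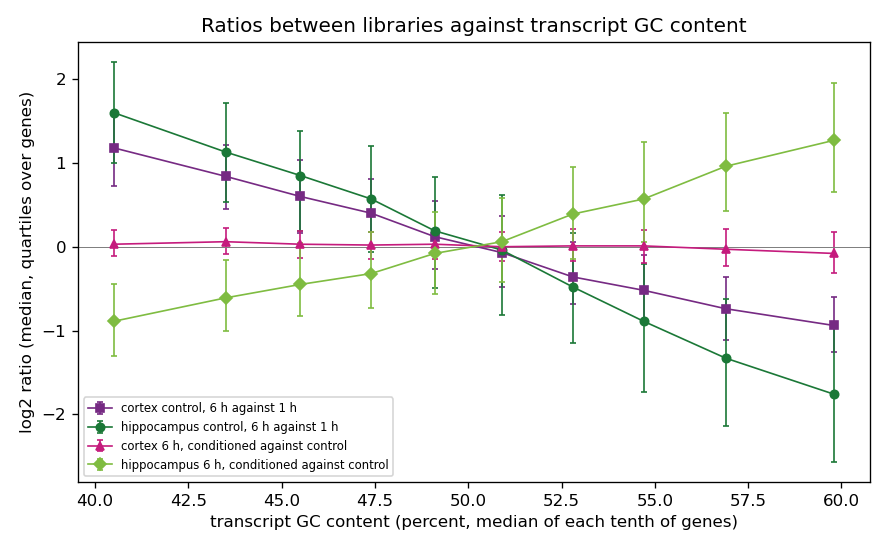
Median log2 ratio of CPM against transcript GC content, in 10 bins of 8427 genes ordered by GC content. The ratio of 6 h to 1 h falls with GC content in the controls of cortex (rank correlation -0.74) and hippocampus (-0.72), and the cortex 6 h ratio of conditioned to control is nearly flat (-0.10).

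The comparison of conditioned with control libraries over both tissues and times asks which messages differ in polyribosome-associated mRNA after fear conditioning in general. No gene passed. Npas4, a neuronal transcription factor induced by activity, stood at 7.39 ± 2.83 CPM in conditioned libraries (n = 3, the pair counted once) and at 18.7 ± 8.24 CPM in controls (n = 4), a log2 difference of -1.17 (SE 0.32) in the fit of 8 libraries and -1.21 (SE 0.30) with the pair summed. Malat1, a nuclear long noncoding RNA, differed by -1.21 (SE 0.43), and Gas5, a noncoding host of small nucleolar RNAs, by -1.24 (SE 0.45). Th, the rate-limiting enzyme of dopamine synthesis and a member of the list of olfactory bulb neurons, differed by 1.49 (SE 0.46). The other fixed activity and stress genes differed by -0.65 (Fos, SE 0.45), -0.55 (Arc, SE 0.41), -0.50 (Junb, SE 0.38), 0.11 (Egr1, SE 0.33), 0.15 (Nr4a1, SE 0.39), 0.23 (Bdnf, SE 0.26), -0.27 (Homer1, SE 0.28), -0.07 (Fkbp5, SE 0.28), -0.01 (Sgk1, SE 0.23) and 0.25 (Camk2a, SE 0.22). The genes of smallest p further included Tmem176a (1.00), Ptpru (0.83), Chrm4, the M4 muscarinic receptor (0.96), Gemin8 (0.89), Ints6l (-1.28), Cntrl (-1.43), Atg10 (-1.16) and Guf1 (-0.95), all with an edgeR adjusted p of 0.958.

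Among the lists, long noncoding RNAs were lower by camera (adjusted p = 0.000182, and 0.508 with an estimated correlation, 13 genes, median -0.40, but 0.52 in the cortex at 1 h with 11 of 13 higher) and chromatin modifiers were lower (adjusted p = 0.0357, and 0.48 with an estimated correlation, Tet2 -0.65). Ionotropic glutamate receptors and their auxiliary proteins were higher (adjusted p = 0.0112, 20 of 24 genes positive, Cacng8 0.96, Grin1 0.43), as were astrocytes and microglia (adjusted p = 0.0312 each) and endothelial and mural cells (adjusted p = 0.042). Late activity-regulated effectors, neuropeptides, histones and voltage-gated potassium channels were higher with an adjusted p of 0.0461 each. The histones were lower in the cortex (median -0.39 at 1 h and -0.46 at 6 h) and higher only in the hippocampus at 6 h (2.63), where the control library had a mean log2 CPM of 1.35 for them. With the pair summed, astrocytes and neuropeptides (adjusted p = 0.0708 each), late effectors (0.158) and potassium channels (0.0959) were not called, and with 1 row per gene camera called 5 lists. With an estimated correlation the 10 lists called with 8 libraries had adjusted p from 0.478 to 0.936, no gene of any list passed over all rows, and 0 passed when adjusted over the list alone. edgeR passed 0 of 15514 rows, with 224 at an unadjusted p under 0.05 where chance gives 776. DESeq2 and limma-voom passed 0 as well, with 200 and 264 such rows. With the counts of both tissues summed, 3 genes passed, all lower: Malat1 (-1.34, SE 0.17, adjusted p = 0.00308), Six3 (-3.01, SE 0.42, adjusted p = 0.00502) and Gas5 (-1.35, SE 0.22, adjusted p = 0.0212). That fit of 4 sums left 1 residual degree of freedom, and each tissue weighed by its counts. At 6 h the hippocampus held 2370973 counts in the control and 4378917 in the conditioned library, and the cortex 5275822 and 5296986. A gene that differs between tissues can therefore differ between the sums. Six3 belongs to the striatal list, whose median was lower in cortex (-0.99 at 1 h and -0.92 at 6 h) and higher in hippocampus (1.22 and 0.59). Without the pair no conditioned library remains at 1 h, so that fit compares training at 6 h alone. In it, with GC and length offsets, 2 passed, C1ql2 (-2.70, SE 0.58, adjusted p = 0.0219) and Meg3 (-2.11, SE 0.43, adjusted p = 0.0115), chosen for naming after their values were seen. C1ql2, a member of the hippocampal list, had 3 counts in cortex outside the pair.

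Within the prefrontal cortex, the tissue named in the design text, conditioned libraries had lower immediate early messages than controls and lower striatal markers, and no gene passed. Arc differed by -1.42 (SE 0.39), Npas4 by -1.63 (SE 0.36), Junb by -1.21 (SE 0.40) and Fos by -1.31 (SE 0.49). Nr4a1 (-0.69, SE 0.31) and Egr1 (-0.60, SE 0.31) were lower by less, and Bdnf (0.52), Fkbp5 (0.38), Camk2a (0.06), Sgk1 (-0.05) and Homer1 (-0.06) lay within 2 SE of 0. Of 36 immediate early genes 27 were lower at 1 h and 30 at 6 h, with camera calling the list lower (adjusted p = 1.911e-08, and 0.553 with an estimated correlation, median -0.32). At 1 h the mean log2 CPM of the list was 4.76 and 4.79 in the pair, between 5.02 in the cortex control and 4.54 in the hippocampus control, where a mixture of both tissues would also lie, and against the mean of these controls its median was 0.04. Adora2a, an adenosine receptor of striatal neurons, differed by -2.34 (SE 0.45), Pde10a, a striatal phosphodiesterase, by -1.15 (SE 0.28) and Drd2 by -1.87 (SE 0.48). The striatal list was lower as a whole (adjusted p = 4.327e-23, and 0.553 with an estimated correlation, 0 of 12 genes positive, 4 passing when adjusted over the list alone). Hippocampal markers were higher (adjusted p = 9.246e-13, and 0.553 with an estimated correlation, 22 of 24 genes positive, median 0.87), with Tspan18 at 3.40, Lct at 2.66 and Slc9a4, outside the list, at 3.93. That difference stood beside the library labelled cortex conditioned 1 h, and at 6 h alone the median of 22 hippocampal markers was 0.00. Globins, markers of blood, were lower in the same libraries (adjusted p = 0.00168, and 0.606 with an estimated correlation, 0 of 5 positive).

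The camera test called 17 lists in cortex in all, and 11 with 1 row per gene. Histones (adjusted p = 2.982e-12), glucocorticoid-responsive genes (adjusted p = 0.00845), clock genes (adjusted p = 0.0125) and chromatin modifiers (adjusted p = 0.0255) were lower, with adjusted p from 0.553 to 0.606 under an estimated correlation. Ionotropic glutamate receptors (adjusted p = 0.000787), the unfolded protein response (adjusted p = 0.01), GABA-A receptors (adjusted p = 0.0127), late effectors (adjusted p = 0.0179, median 0.02 and 0.00 with RLE factors), endothelial cells and microglia (adjusted p = 0.0212 each), astrocytes (adjusted p = 0.0366), thalamic markers and potassium channels (adjusted p = 0.04 each) were higher. With an estimated correlation the adjusted p of the 17 lists ran from 0.553 to 0.799. edgeR passed 0 of 16304 rows, with 110 at an unadjusted p under 0.05, and DESeq2 and limma-voom passed 0 with 44 and 114. Chrna7 (1.31), Il16 (2.04) and Cd4 (-1.69) completed the genes of smallest p, all with an adjusted p of 1. Leaving out the hippocampus conditioned 6 h, hippocampus control 1 h or hippocampus conditioned 1 h library gave 56, 22 or 21 rows, and leaving out the hippocampus control 6 h, cortex conditioned 6 h or cortex control 6 h library gave 3, 4 or 3.

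Within the hippocampus no gene passed in edgeR, and long noncoding RNAs were lower while histones, neuropeptides and striatal markers were higher as lists. Malat1 differed by -2.21 (SE 0.34), Gas5 by -2.01 (SE 0.51) and Meg3, an imprinted noncoding RNA, by -1.76 (SE 0.55). Olfm2, a secreted olfactomedin, differed by 2.30 (SE 0.32), and Cpne5 (2.11), Rasgef1c (2.90), Kcnh2, a potassium channel (1.81), and Cacna1g, a T-type calcium channel (1.53), were also higher. Orc6 (-1.72), Rap1a (-1.64), Cep70 (-2.44) and Suz12 (-1.62) were lower. Of the activity genes Nr4a1 (1.12, SE 0.34) and Egr1 (0.85, SE 0.32) were higher in conditioned libraries, and Fos (0.35), Arc (0.33), Junb (0.28), Bdnf (-0.05), Sgk1 (0.05), Homer1 (-0.49), Fkbp5 (-0.50), Npas4 (-0.60) and Camk2a (0.44) lay within 2 SE of 0. At 1 h both lay between the controls of the tissues: Egr1 stood at 437.2 CPM in the hippocampus control, 1089 CPM in the library labelled hippocampus conditioned 1 h and 1601 CPM in the cortex control, and Nr4a1 at 43.7 CPM, 75.5 CPM and 106.1 CPM.

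Long noncoding RNAs were lower in hippocampus by camera (adjusted p = 0.000111, and 0.863 with an estimated correlation, 1 of 13 genes positive, 5 passing when adjusted over the list alone). Histones were higher (adjusted p = 6.62e-09, median 0.73), as were neuropeptides (adjusted p = 0.0402, and 0.0397 by fry, Penk 1.18, Tac1 1.85) and striatal markers (adjusted p = 0.0442, 6 of 12 passing when adjusted over the list alone, Ppp1r1b 1.89, Drd1 1.73), which include Penk and Tac1. All 4 lists had an adjusted p of 0.863 with an estimated correlation. At 1 h markers of hippocampal excitatory neurons (median -0.78, 19 of 22 lower) and oligodendrocytes (-0.45, 14 of 14 lower) moved beside them, and the long noncoding RNAs had a mean log2 CPM of 4.36 in the cortex control and 5.60 in the hippocampus control. The histone values moved with the hippocampus control 6 h library, where their mean log2 CPM was 1.35 against 2.41 to 4.75 elsewhere. edgeR passed 0 of 16304 rows at a lowest adjusted p of 0.409, with 1969 at an unadjusted p under 0.05. DESeq2 passed 2, Olfm2 (2.28) and Malat1 (-2.26), with 1521 such rows, and limma-voom 0 with 2149. The edgeR count rose when any hippocampus library was left out. Such a fit drops the whole stratum of that library. The contrast then rests on 1 conditioned and 1 control hippocampus library, and its spread comes from the cortex libraries. Those counts therefore do not test training in hippocampus.

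The training by tissue interaction tests whether the training differences of the 2 tissues differ. No gene passed. The conditioned 1 h pair lay between the 1 h controls in markers of both tissues, and such a position gives opposite differences in the tissues: at 1 h the list medians in cortex and hippocampus were -0.27 and 0.29 for immediate early genes, -0.99 and 1.22 for striatal markers and 1.65 and -0.78 for hippocampal markers. At 6 h, without the pair, the medians were -0.38 and 0.49 (22 of 36 higher in hippocampus), -0.92 and 0.59, and 0.00 and -0.25. The hippocampus ratio at 6 h carries a GC trend (rank correlation 0.65). The immediate early genes were higher in hippocampus relative to cortex by camera (adjusted p = 0.000201, and 0.978 with an estimated correlation, 27 of 36 genes positive, median 0.92), with Nr4a1 at 1.82 (SE 0.46), Arc at 1.76 (SE 0.55), Fos at 1.66 (SE 0.77), Junb at 1.49 (SE 0.58), Egr1 at 1.45 (SE 0.45) and Npas4 at 1.03 (SE 0.53). Bdnf (-0.57), Fkbp5 (-0.87), Homer1 (-0.43), Sgk1 (0.10) and Camk2a (0.38) lay within 2 SE of 0. Striatal markers (adjusted p = 3.772e-10), histones (2.927e-15), clock genes (0.012) and globins (0.0175) were higher, and hippocampal markers (1.101e-06), long noncoding RNAs (0.00108) and GABA-A receptors (0.012) were lower. These 8 lists had an adjusted p of 0.978 with an estimated correlation. Olfm2 (2.33), Cpne5 (2.73), Rasgef1c (3.24), Adora2a (7.73, SE 1.53), Ppp1r1b (3.06), Tspan18 (-4.72), Slc9a4 (-4.70), Stk3 (-2.32), Kctd4 (-2.01) and Malat1 (-2.02) had the smallest p with an adjusted p of 0.687. edgeR, DESeq2 and limma-voom passed 0 rows, with 1033, 682 and 1170 at an unadjusted p under 0.05. Leaving out any hippocampus library or either cortex 6 h library brought rows past the threshold. That tissue then enters with 1 conditioned and 1 control library, so those rows do not test the interaction.

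At 1 h, both conditioned libraries are the pair, so the comparison sets 1 sample, between the tissues in its markers, against 2 controls, and no gene passed. Fos (0.02, SE 0.48), Egr1 (0.35, SE 0.49), Nr4a1 (0.15, SE 0.54), Arc (-0.40, SE 0.55), Junb (-0.41, SE 0.53), Npas4 (-0.85, SE 0.46), Bdnf (0.32), Sgk1 (0.34), Fkbp5 (-0.21), Homer1 (0.11) and Camk2a (0.11) lay within 2 SE of 0. Th (1.71, SE 0.60), Aifm2 (1.23), Fkbp9 (1.21), Ext2 (0.85) and Podxl were the higher genes of smallest p and BC048507 (-1.27), Cntrl (-1.84), Glrx5 (-1.16), Bend5 (-1.44) and Cys1 (-1.49) the lower ones, with an adjusted p of 1. Camera called cytosolic ribosomal proteins (adjusted p = 2.046e-11, 6 of 83 genes positive), oxidative phosphorylation (2.504e-06), mitochondrial ribosomal proteins (1.833e-05) and histones (0.00713) lower, with adjusted p from 0.496 to 0.772 under an estimated correlation. The first 3 of these were lower in the hippocampus alone (medians -0.58, -0.47 and -0.41, against 0.00, -0.02 and 0.00 in cortex). It called ionotropic glutamate receptors (1.833e-05, 21 of 24 positive), cortical excitatory neurons (0.000129), late effectors (0.000215), potassium channels (0.000807), astrocytes (0.00088), hippocampal excitatory neurons (0.0013), neuropeptides and thalamic neurons (0.00646 each), GABA-A receptors (0.00895), endothelial cells (0.0244) and general markers of excitatory neurons (0.0481) higher. With an estimated correlation the 11 higher lists had adjusted p from 0.477 to 0.636. The fit averages log2 differences over the tissues, so a sample midway in CPM lies higher for genes of either tissue. Against the mean of the 1 h controls, hippocampal markers had a median of -0.17, with 17 of 22 lower. Cortical markers had 0.09, with 13 of 20 higher. The call of hippocampal markers as higher therefore depends on the scale. With the pair summed to 1 library, 14 of these 15 lists were called in the same direction, and neuropeptides were not. Choroid plexus and olfactory bulb neurons were called higher as well, and neither passed with an estimated correlation. The low-count filter of that fit kept rows expressed in 1 library alone, since the summed pair formed a group of its own. It tested 16990 rows against 16304 with 8 libraries, and only so did the olfactory list reach 5 rows. Members that entered through the pair are high in it by selection, so the olfactory call is no test of that list. edgeR, DESeq2 and limma-voom passed 0 rows, with 30, 8 and 25 at an unadjusted p under 0.05, and edgeR passed 5 without the cortex conditioned or control 1 h library.

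At 6 h, conditioned libraries had lower long noncoding RNAs and lower Fos and Npas4 than controls, and no gene passed. For Fos this was the cortex, where the control had 13.5 CPM and no other 6 h library more than 2.73 CPM, while in the hippocampus it had 6 counts in the conditioned library and 4 in the control. Gas5 differed by -1.91 (SE 0.56), Meg3 by -1.74 (SE 0.54), Fos by -1.80 (SE 0.62) and Npas4 by -1.52 (SE 0.49). Junb (-0.63), Arc (-0.73), Egr1 (-0.11), Nr4a1 (0.18), Sgk1 (-0.37), Bdnf (0.16), Homer1 (-0.66), Fkbp5 (0.07) and Camk2a (0.39) lay within 2 SE of 0. Slc22a17 (1.59), Chst8 (2.22), Tspan6 (2.13), Tbl3 (1.62) and Get3 (1.80) were higher, and Phf10 (-1.42), Dimt1 (-1.69) and Zcchc17 (-1.33) lower, all with an adjusted p of 0.874. Camera called histones (adjusted p = 5.597e-06), oxidative phosphorylation (0.00138), cytosolic ribosomal proteins (0.00868) and mitochondrial ribosomal proteins (0.0242) higher, and long noncoding RNAs (3.567e-05, 1 of 13 genes positive), chromatin modifiers and translational repressors (0.0187 each) and GABA-A receptors (0.0304) lower. These 8 lists had an adjusted p of 0.818 with an estimated correlation. In the cortex histones were lower (median -0.46) and GABA-A receptors higher (0.22), so these calls rest on the hippocampus libraries (2.63 and -0.80). The hippocampus 6 h libraries differed in base composition along with these groups, their log2 ratio having a rank correlation of 0.65 with GC content. edgeR, DESeq2 and limma-voom passed 0 rows, with 478, 464 and 579 at an unadjusted p under 0.05. Without the cortex conditioned or control 6 h library edgeR passed rows. The 6 h contrast then rests on 1 conditioned and 1 control hippocampus library, so those rows do not test training.

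The training by time interaction tests whether the training differences at 6 h and 1 h differ. No gene passed, the simulated counts gave no power at a fold of 4, and the fixed genes ranged from Fos at -1.82 (SE 0.78) through Homer1 (-0.77), Sgk1 (-0.71), Npas4 (-0.67), Egr1 (-0.46), Arc (-0.33), Junb (-0.21), Bdnf (-0.16) and Nr4a1 (0.03) to Fkbp5 and Camk2a (0.27 each). Dguok (2.14), Tbl3 (1.75), Phf1 (1.81), Guk1 (1.63), Tmem242 (2.54), Tlr3 (-2.12), Aifm2 (-2.07), Sppl3 (-1.74), Zfp277 (-1.95) and Dimt1 had the smallest p with an adjusted p of 0.999. Camera called cytosolic ribosomal proteins (adjusted p = 3.025e-09), histones (4.988e-09), oxidative phosphorylation (2.717e-08), mitochondrial ribosomal proteins (6.218e-06) and proteasome subunits (0.0185) higher, with adjusted p from 0.623 to 0.675 under an estimated correlation. It called GABA-A receptors (0.000667), cortical excitatory neurons (0.000915), long noncoding RNAs (0.00194), thalamic neurons (0.00291), translational repressors (0.0134) and glucocorticoid-responsive genes (0.0211) lower. With an estimated correlation the 6 lower lists had adjusted p from 0.623 to 0.676. edgeR, DESeq2 and limma-voom passed 0 rows, with 105, 62 and 102 at an unadjusted p under 0.05, and edgeR passed 128 without the cortex conditioned 6 h library and 1 without the hippocampus conditioned or control 1 h library.

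The cortex at 6 h is the stratum in which conditioned and control libraries were closest in base composition, with a rank correlation of their log2 ratio with GC content of -0.10. Immediate early messages were lower in the conditioned library and those of the unfolded protein response higher. Fos had 14 counts in the conditioned library and 70 in the control, a log2 ratio of -2.31 with a 95% counting interval of -3.25 to -1.47. Arc had 62 against 276 (-2.14, interval -2.56 to -1.74), Npas4 37 against 130 (-1.80, -2.37 to -1.26) and Junb 11 against 40 (-1.85, -2.96 to -0.86). Nr4a1 (-0.94, -1.40 to -0.50), Egr1 (-0.58, -0.66 to -0.50) and Sgk1 (-0.39, -0.72 to -0.06) were lower by less, and the intervals of Bdnf (0.39), Homer1 (-0.05), Fkbp5 (0.29) and Camk2a (-0.02) included 0. Of 36 immediate early genes 30 were lower (median -0.38, percentile 0 among random lists), as were 18 of 21 glucocorticoid-responsive genes (median -0.35) and 50 of 56 histones (median -0.46). Of 20 genes of the unfolded protein response 15 were higher (median 0.26, percentile 100). Beside them, 10 of 10 striatal markers (median -0.92) and 5 of 5 globin rows (median -0.89) were lower, so tissue composition and blood content moved with the immediate early genes.

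Only 14 of 6369 genes differed by at least a fold of 2 in the cortex at 6 h. The largest ratios were Lars2, the mitochondrial leucyl-tRNA synthetase (-2.57), Arc (-2.10 with the prior count), Ddit4, a stress-induced inhibitor of mTORC1 (-1.68), Gas5 (-1.36) and Spr, sepiapterin reductase (-1.34), and Cd99l2 (1.19), Lmo4 (1.06), Ldha, lactate dehydrogenase A (1.02), Mrpl36 (1.01) and Slc22a17 (1.01). GABA-A receptors (median 0.22), interneuron markers (0.21), cytosolic ribosomal proteins and proteasome subunits (0.15 each) lay at percentiles of 99.2 to 100, and long noncoding RNAs (-0.26) at 0.3. These values have no replicate check.

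In the hippocampus at 6 h, 1940 genes differed by at least a fold of 2, 1133 higher in the conditioned library. H2bc12 (4.87), H2bc23 and H4bc24 (4.50 each), H2bc7 (4.49) and H2bc15 (4.32), all histones that share reads, were the highest, and Kif5c (-4.30), Cdr1, whose antisense circular RNA cannot be told apart from it without strand (-3.13), Ppig (-2.95), Pter (-2.93) and Mphosph8 (-2.78) the lowest. Of the activity genes Nr4a1 (1.69, interval 0.78 to 2.74), Arc (0.74, 0.25 to 1.25) and Egr1 (0.36, 0.19 to 0.53) were higher, and Npas4 (-1.16, -2.15 to -0.16) and Homer1, a postsynaptic scaffold protein (-1.28, -1.48 to -1.08), were lower. Camk2a, the alpha subunit of calcium/calmodulin kinase II, was higher (0.79, interval 0.74 to 0.83), and the intervals of Fos (-0.73), Junb (0.79), Bdnf (-0.08), Fkbp5 (-0.15) and Sgk1 (-0.37) included 0. The median of the histone list was 2.63, of oxidative phosphorylation 0.73 and of GABA-A receptors -0.80, beside the GC trend of this ratio. GC content and length accounted for 42.5% of its variance, and the counting intervals of single genes leave that trend out. With GC and length offsets the 6 h training value over both tissues went from -0.73 to -1.28 for Arc and from -0.63 to -1.27 for Junb. Homer1 in hippocampus over both times went from -0.49 to -0.05.

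At 1 h, 55 genes differed by at least a fold of 2 between the library labelled cortex conditioned 1 h and its control, 47 of them higher, and 184 in hippocampus, 109 of them higher. In cortex Shisa6 (3.69), St18 (2.50), Prox1 (1.98), Pcdh20 (1.84) and Slit1 (1.78) were highest and Ppp1r1b (-1.42), Trib1 (-1.11), Pde10a (-1.09), Klf10 (-1.07) and Dusp1 (-1.07) lowest. In hippocampus Stard8 (2.92), Cpne5, Cobl (2.37), Cckbr (2.35) and Lamp5 (2.33) were highest and Malat1 (-2.08), Gas5 (-1.61), Tmsb4x (-1.46), Nnat (-1.45) and Gjc3 (-1.43) lowest. Markers of the other tissue moved with both ratios: hippocampal markers had a median of 1.65 in cortex and cortical markers 0.56 in hippocampus.

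**Figure D4:**
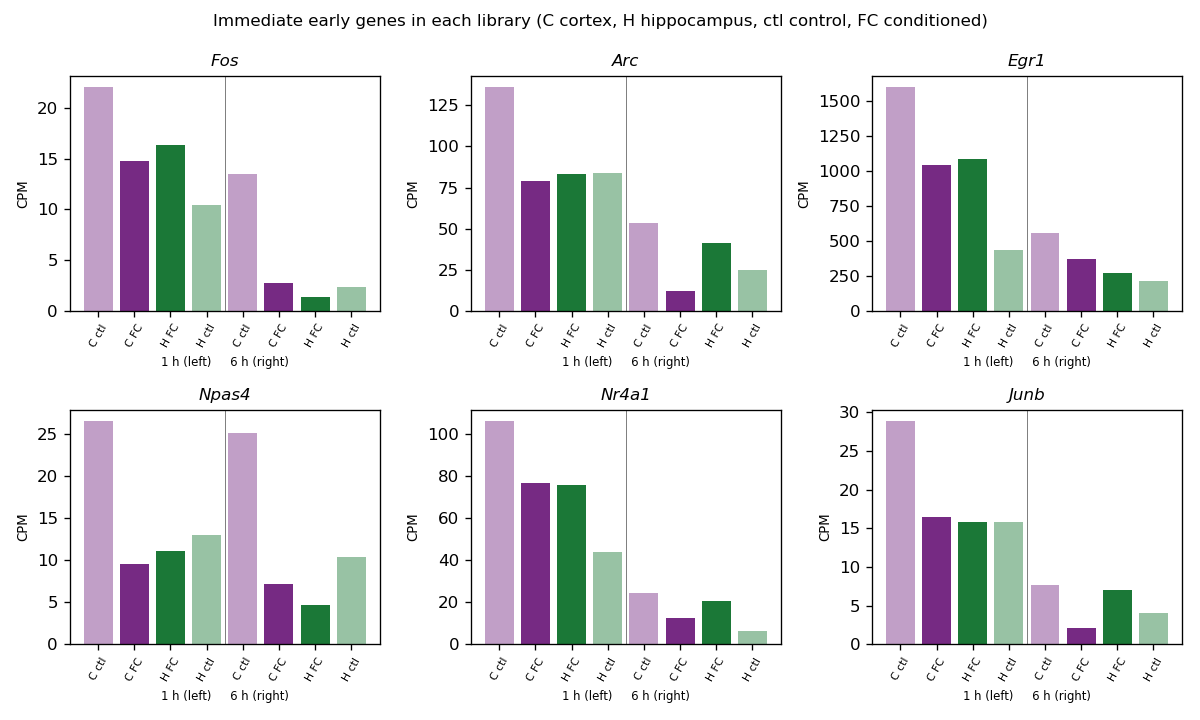
CPM of Fos, Arc, Egr1, Npas4, Nr4a1 and Junb in each of the 8 libraries, 1 bar per library with an axis from 0. In cortex at 6 h, Fos stands at 2.73 CPM in the conditioned library and 13.5 CPM in the control.

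Lists that camera called in no comparison with 8 libraries were synaptic vesicle and release genes, choroid plexus, translation initiation and elongation factors, heat shock proteins and chaperones, oligodendrocyte precursors, interneurons, transfer RNA synthetases and postsynaptic scaffold genes, with a lowest adjusted p of 0.0526. Markers of olfactory bulb neurons and ependymal cells and the mitochondrially encoded genes had fewer than 5 tested rows there and were not tested. With the pair summed, olfactory bulb neurons were also called higher in conditioned libraries at 6 h (adjusted p = 0.000708, and 0.802 with an estimated correlation). The list reached 5 rows there only through a filter that kept rows expressed in 1 library.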

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

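The tests of the 3 patterns weighed here were chosen only after the results were seen, except the test of GC content in the cortex at 6 h and the counts of other splits of the 8 libraries, which were set down before these tests were run but with the real counts known.

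The libraries labelled cortex and hippocampus conditioned 1 h agreed within sampling noise, with a mean variance ratio of 1.06 where the next pair had 4.76. A single tissue under a wrong label is argued against by the position of the library labelled cortex, 0.46 on hippocampus-high genes with quartiles of 0.38 and 0.55, where 1 tissue would lie near 0 or 1. A candidate explanation is that 1 library or 1 pool of both tissues stands under both labels, and the midway position beside the ratio of 1.06 is what it would give. Separate libraries of tissues that training had made alike cannot be told apart from it: the 4.9% of genes with an unadjusted p under 0.05 between the pair restates their agreement, and no combination has a replicate to show how far separate libraries lie apart. If tissues were mixed, where that took place cannot be read from the counts.

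Libraries at 6 h differed from those at 1 h in 7146 of 15514 rows, a difference that followed GC content. Of 6965 called rows with known GC content, 1442 passed after the GC and length trend was removed, so GC and length bias is a candidate source of most of the calls. For the lower immediate early genes it cannot be told apart from a change of these genes: their median over 40 rows went from -1.10 to -0.41 (quartiles -0.96 and 0.04, 30 rows below 0), with a camera adjusted p of 0.000771, one of 0.964 with an estimated correlation and one of 0.159 by fry. A library batch that follows the time is open as well, since the nearest 1 h and 6 h libraries were 0.82 apart in their rank correlation with GC content and no library of one time lay within the range of the other. Time after the session and time of day stay among the open explanations, as untested.

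Immediate early genes were lower in the conditioned cortex library at 6 h, by -0.55 in the mean log2 CPM of the list. GC content and length are argued against, since the list's median log2 ratio was -0.38 before and -0.38 after their trend was removed. Less striatal tissue in the conditioned library may be the source of the lower fixed genes: their median over 6 genes was -1.69, between the lowest of 10 striatal markers (-2.04) and their lower quartile (-1.19), which neither excludes it nor shows it. The bound of that test was revised after the values were seen, so that it could exclude the explanation at all. Fear conditioning cannot be told apart from a difference between any 2 samples here, because the -0.55 rests on 1 conditioned and 1 control library.

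For the training effect over both tissues and times and for tissue with 8 libraries, the real count was 0, which all 32 splits that could be estimated reach by construction (highest other 0), so these counts say nothing about chance. In each case 3 further splits could not be estimated. For time 1 of 32 splits, the real one, reached 7146 rows and the highest other gave 0. This does not exclude chance, even if the conditioned 1 h pair were separate samples. Each block holds 1 library of each time, and most of the splits do not divide every block. A large time difference also enters the residual of the other splits, which lowers their counts. With the pair summed to 1 library, 2 of 34 splits gave as many (real 6063, highest other 7025), so chance is not excluded. The split with 7025 put the hippocampus conditioned 6 h library with the 1 h ones. For training with the pair summed the real count of 0 was again reached by all 34 splits, which says nothing about chance. The highest other gave 3473, from a split that set the other 6 h libraries apart from the hippocampus control 6 h library and those of 1 h, which points to a structure of the samples. In each of these sets of 7 libraries 1 further split could not be estimated. For tissue with 6 libraries the 10 splits are too few for a share under 0.05, with 541 rows for the real split and 0 for the highest other.

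Measures of 4 libraries of a tissue, a time or a training state were screened for a library far from the others, by the gap to its nearest neighbour over the whole range. Of 56 such tests 5 passed, where chance passes about 1 in 20, or 2.8. Groups holding both libraries of the conditioned 1 h pair were dropped after the first screen was seen, because the pair counts once and leaves 3 samples. The hippocampus control 6 h library stood apart in the share of its top gene, Kif5c (8.01%), among hippocampus libraries (gap 0.891, nearest 1.48%) and among 6 h libraries (gap 0.85, nearest 2.46%). It stood apart in the genes with counts at equal depth among 6 h libraries (13606 against 14307, gap 0.9) and in Homer1 among hippocampus libraries (238.9 CPM against 107.2 CPM, gap 0.872). The cortex control 6 h library stood apart in Fos among 6 h libraries, with 13.5 CPM against 2.73 CPM for the nearest (gap 0.89).

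Between tissues, some fixed genes had opposite directions at both times, a difference that was not tested by itself beyond the interaction fit. At 1 h each of them lay between the controls of the tissues in both conditioned libraries, which agree within sampling noise. Opposite directions there follow from this position. Only the 6 h values are free of it, and in hippocampus those carry a trend with GC content (rank correlation 0.65). The smallest gap between a cortex and a hippocampus ratio was 1.25 for Nr4a1, 0.94 for Egr1, 0.42 for Fkbp5 and 0.40 for Bdnf. Between times, Sgk1 had opposite directions with a smallest gap of 0.63, likewise untested.

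By camera with the preset correlation, the training difference differed between tissues for histones (adjusted p = 2.927e-15), striatal markers (3.772e-10), hippocampal excitatory neurons (1.101e-06), immediate early genes (0.0002006), long noncoding RNAs (0.001077), clock genes and GABA-A receptors (0.01196 each) and globins (0.01752), and all had an adjusted p of 0.978 with an estimated correlation. The position of the pair between the 1 h controls adds to those of striatal and hippocampal markers, immediate early genes, long noncoding RNAs and clock genes. It differed between times for cytosolic ribosomal proteins (adjusted p = 3.025e-09), histones (4.988e-09), oxidative phosphorylation (2.717e-08), mitochondrial ribosomal proteins (6.218e-06), GABA-A receptors (0.0006673), cortical excitatory neurons (0.0009153), long noncoding RNAs (0.00194), thalamic neurons (0.002907), translational repressors (0.01344), proteasome subunits (0.01853) and glucocorticoid-responsive genes (0.02111), with adjusted p from 0.623 to 0.676 under an estimated correlation.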

How the results depend on the processing

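The alternatives with 5, 6 or 7 libraries, those with GC and length offsets, and the list tests with 1 row per gene, 6 or 7 libraries were chosen after seeing the data. The cause of the differences was not tested unless fewer samples make it. For training over both tissues and times, 2 rows passed with 6 libraries and GC and length offsets, 3 with tissues summed and 0 in the other alternatives. The fits of 6 libraries hold the training difference at 6 h alone. For training in hippocampus DESeq2 passed 2. For tissue, where the reported 8-library count was 0, DESeq2 passed 245, 7 libraries 527, 6 libraries 541, 5 libraries 858 and 6 libraries with offsets 958. For time, where it was 7146, offsets left 2151, 6 libraries 3326, 5 libraries 1148 and 6 libraries with offsets 939, while DESeq2 (6921), limma-voom (7288) and upper-quartile factors (7061) stayed within 1.5 times. Of 91 list calls by camera over the 9 comparisons, 0 were made with an estimated correlation and 2 by fry, against 90 with RLE factors, 78 with the GC trend removed and 74 with 1 row per gene. With 6 libraries camera made 31 calls where 8 libraries made 28 over the same 3 comparisons, 21 of them shared, and with the pair summed 64 against 62 over 6, with 56 shared. With 1 row per gene the calls went from 10 to 5 for training over both tissues and times and from 17 to 11 in cortex.

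With each library left out in turn, training over both tissues and times stayed at 0. Other counts ranged from 0 to 56 for training in cortex, from 0 to 5646 in hippocampus, from 0 to 4727 for the training by tissue interaction, from 0 to 5 at 1 h, from 0 to 1414 at 6 h, from 0 to 128 for the training by time interaction, from 0 to 522 for tissue and from 2938 to 7866 for time, and list calls from 81 to 125. The libraries that moved a count by over 1.5 times are named beside each comparison in the report. A fit without 1 library leaves its stratum with a lone sample, assumed to vary like the others, and that stratum drops out of the contrast. Where the library belongs to the tissue or time tested for training, 1 conditioned and 1 control library carry the contrast. The spread then comes from the other tissue or time, so such counts do not test training. Genes at least a fold of 2 apart within single combinations numbered 2193 in all, 2118 to 2273 under other prior counts and scaling.

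Of 186 results for named genes under 3393 alternatives, 3166 kept their side of the threshold without a reversal (3058 with the same direction), 213 became stronger, 7 weaker and 7 reversed. A reversal was counted where either value was called or the shift exceeded 2 SE, and the other 108 were sign changes within 2 SE that involved no call. Reversed were Homer1 in hippocampus (-0.49, range -1.27 to 0.33), with 0.33 without the hippocampus control 6 h library, and Egr1 at 1 h (0.35, range -0.64 to 1.33), with -0.64 without either hippocampus 1 h library. Junb at 6 h (-0.63, range -1.86 to 0.80) was 0.79 or 0.80, and Arc at 6 h (-0.73, range -2.17 to 0.75) was 0.74 or 0.75, without the cortex conditioned or control 6 h library. In each case the library left out removes its stratum from the contrast. Depth limits low messages: Fos had 4 and 6 counts in the hippocampus 6 h libraries, and its interval of -2.80 to 1.54 shows that a difference was not detectable at this depth.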

Other observations

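The values here were chosen for description after the results were seen.

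Set against the mean of the 1 h controls of both tissues, the conditioned 1 h pair showed lower messages of ribosomal proteins and oxidative phosphorylation and higher messages of glutamate and GABA-A receptors and potassium channels, as a description of 1 sample against 2 libraries. Of 82 cytosolic ribosomal protein genes 79 were lower (median log2 ratio -0.33), as were 71 of 76 oxidative phosphorylation genes (median -0.28), 61 of 75 mitochondrial ribosomal protein genes (median -0.22) and 18 of 20 chaperones (median -0.17). Ionotropic glutamate receptors (median 0.19), GABA-A receptors (0.22) and voltage-gated potassium channels (0.18) were higher, each at percentile 100 among random lists. Microglial markers had a median of 0.32, genes of the unfolded protein response 0.14 and globins -0.43. Of 6369 genes 1 differed by at least a fold of 2, Malat1 (-1.38), followed by Gas5 (-0.98), Otud6b (-0.85), Tmsb4x, the actin-binding thymosin beta4 (-0.82), and Nnat, neuronatin (-0.79). The largest rises in ratio were Ext2, a heparan sulfate polymerase (0.83), Astn2 (0.71), Ddit4l (0.71), Exph5 (0.70) and Slc7a5, an amino acid transporter (0.69). The falls of the ribosomal protein and oxidative phosphorylation lists come from the hippocampus control: cytosolic ribosomal proteins had a mean log2 CPM of 4.80 and 4.78 in the pair, 4.78 in the cortex control and 5.40 in the hippocampus control, and oxidative phosphorylation 5.80 and 5.82, 5.83 and 6.25. How far the pair lies towards each tissue differs between genes, so a gene that differs between tissues, as Malat1 and Gas5 do, can depart from the mean through that position alone.

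Long noncoding RNAs were lower in the conditioned member of 3 of the 4 tissue and time combinations. Their median over 13 genes was -0.26 in the cortex at 6 h, -0.74 in the hippocampus at 1 h and -0.61 in the hippocampus at 6 h, with 11 of 13 genes lower in each, and 0.52 in the cortex at 1 h, with 11 of 13 higher. In the 1 h controls themselves the list's mean log2 CPM was 4.36 in cortex and 5.60 in hippocampus, and in the pair 4.80 and 4.85.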
